A study of Homo sapiens with 8 samples.

How the data were processed

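RNA from 8 libraries of T47D cells was analysed, 4 from cells given vehicle and 4 from cells given karanjin, with groups and replicate numbers taken from the sample titles. Per the labels' protocols, cells were seeded, moved after 48 h to medium without phenol red that held 10% charcoal-stripped serum, and treated after a further 24 h for 24 h. Per the labels' protocols, mRNA was captured and libraries were made with the KAPA RNA Hyper kit and sequenced on a NextSeq instrument as paired reads of 150 nt. Nothing in the sources used here says that the replicates were separate cultures, so p-values measure only the spread between these samples, which may be technical.

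The deposited table holds raw read counts per Ensembl gene ID, 1 column per library, with no normalization. Per the submitters' processing notes, FastQC 0.11.5, Trimmomatic 0.36, STAR 2.7.6a, featureCounts 2.0.0 and the build GRCh38 were used; the settings, strand mode and annotation release were not given in the sources used here. The 58735 gene IDs were matched to GENCODE release 29 on GRCh38, which holds the same IDs with 0 missing, and positions, transcript lengths and GC content came from that release, using the longest transcript of each gene. A gene name table gave symbols for 41937 IDs. All 37 mitochondrial genes had 0 counts in every library, so mitochondrial transcripts could not be used as a sign of RNA quality. The lowest chi-square per gene between 2 libraries was 2.13 (vehicle replicates 1 and 4), so no pair agreed within sampling noise and each library counted as 1 sample.

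Counts were tested in R 4.3.3 with edgeR 4.0.16. Genes were filtered with filterByExpr, libraries were scaled with TMM factors, and the quasi-likelihood test (glmQLFit with robust fitting, glmQLFTest) compared karanjin with vehicle with group as the only term. Benjamini-Hochberg adjustment covered the 14565 genes tested, and a gene was called at an adjusted p under 0.05. Standard errors are the log2 fold change divided by the square root of the F statistic. CPM values are counts scaled to the TMM-adjusted library size by the cpm function of edgeR and were computed here from the deposited counts. The level that 3 counts give in each library served as the floor, and it covers counting error only.

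The 32 gene lists were written from general knowledge, and 27 of them had the 5 or more tested members needed. They cover estrogen-induced and estrogen-repressed genes, aryl hydrocarbon receptor targets, NRF2 targets, the unfolded protein response, the ATF4 amino acid response, cholesterol synthesis, lipogenesis, S phase, G2/M, p53 targets, hypoxia and glycolysis, interferon, inflammation, glucocorticoid, progesterone and androgen receptor targets, luminal identity, mesenchymal genes, heat shock, drug metabolism, apoptosis, autophagy and lysosome, immediate early genes, the nuclear respiratory chain, ribosomal proteins, ribosome biogenesis, replication histones and basal epithelial markers. Lists of metallothioneins, mitochondrial mRNAs, and markers of fibroblasts, leukocytes and endothelial cells had too few tested members. Lists were compared with all other genes by camera in limma 3.58.1 with its preset correlation of 0.01, and Benjamini-Hochberg adjustment covered the 27 lists. Counts described as adjusted over the list alone adjust the edgeR p-values of that list's members only.

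The groups, tests, gene lists, alternatives and the rule for named genes were fixed before the data were examined. Genes were named if they passed the threshold with a mean of at least 5 CPM in the higher group and no overlap between the groups' libraries, taking up to 10 by fold change and 5 by p in each direction; if they were among the 4 members with the smallest p of a list described; or if they were among ESR1, PGR, GREB1, TFF1, CYP1A1, CYP1B1, AHR, AHRR and TIPARP. A gene that the rule names is not reported here. The genes LINC02568 and SLC7A5 were named after their values were seen.

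Alternatives were RLE and upper-quartile scaling, no filter, a filter of 1 CPM in 4 libraries, DESeq2 1.42.0, limma-voom, fits without robust estimation and with the older quasi-likelihood method, the replicate number as a block, each library left out in turn, and, for lists, an estimated correlation and fry. Chosen after seeing the data were a correction that removed from each library its trend on transcript GC content and log2 length (natural splines with 5 degrees of freedom each, fitted to log2 CPM with a prior count of 2 and used as offsets), the same for GC alone, the correction joined with the replicate block, with an estimated correlation or with the loss of vehicle replicate 2, the replicate block without that library, and fits without vehicle replicates 2 and 3 together. The correction also removes any true effect that follows GC content. Exons of several named genes overlap those of another gene, so that their counts are uncertain where the strand mode is not given: this holds for CYP1B1, NFE2L2, TIPARP, AHR, AHRR, ESR1, PGR, ERBB2, IGFBP5, LIG1, MCM2, LSS, TM7SF2, FADS2, SREBF1, NDUFS7, ATP5F1E, ELF3, KRT18, NUF2, BORA, JUNB, IER3, SLC7A5, BCL2L1 and ALDH1L2. Of the genes tested, 9 had no transcript sequence and were given the median GC content.

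The scripts were tested on simulated counts for this comparison, in which 200 genes were changed by known folds. Without a GC trend, edgeR tested 14241 genes and recovered 59.7% of those changed 1.5-fold, 92.5% at 2-fold and 100% at 4-fold, with 8 false calls. With the measured GC trends added it tested 14227 genes and recovered 20.9% at 1.5-fold, 77.6% at 2-fold and 100% at 4-fold with 47 false calls, and with the correction 53.7%, 88.1% and 100% with 13. DESeq2 gave 252 false calls on the simulated counts with those trends. Apart from the trends, genes were drawn independently with the spread of the corrected fit, so other structure between libraries was left out. The real counts gave 4 calls in all by the main edgeR fit, so the simulation does not reproduce them. The shares recovered may be too high for these data.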

Results

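Polyadenylated RNA was sequenced from T47D cells, an established luminal breast cancer line that expresses the estrogen and progesterone receptors. The cells spent 24 h in medium without phenol red, supplemented with serum stripped of steroids by charcoal, and were then exposed for 24 h to 10 µM karanjin, a furanoflavonoid, or to 0.1% DMSO as vehicle. The question was which transcripts karanjin changes across the genome. There were 4 vehicle and 4 karanjin libraries. Reads assigned to genes totalled 7060347, 12053654, 8272982 and 8694689 in vehicle replicates 1 to 4, and 9247791, 7966175, 8690146 and 8735450 in karanjin replicates 1 to 4. Between 23244 and 24037 genes had at least 1 read in a library, and 14565 genes passed the filter on low counts and were tested.

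Karanjin raised the transcripts of 3 members of the cytochrome P450 family 1, the enzymes known best as targets of the aryl hydrocarbon receptor, and that of the adhesion molecule CADM1. CYP1A1, which oxidizes polycyclic aromatic hydrocarbons, rose from a normalized CPM (reads scaled to library size) of 18.2 ± 4.08 (SD, n = 4) with vehicle to 108 ± 13.4 with karanjin. CYP1A2, its neighbour on chromosome 15, rose from 1.85 ± 0.852 to 8.37 ± 0.884 CPM. CYP1B1, which hydroxylates estradiol, rose from 331 ± 39.0 to 660 ± 30.6 CPM. CADM1 rose from 150 ± 12.7 to 256 ± 12.5 CPM. For each of these genes the lowest karanjin library lay above the highest vehicle library.

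These 4 genes were all that passed in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and 2 of them, CYP1A1 and CYP1A2, changed at least 2-fold. The log2 fold change of CYP1A1 (ENSG00000140465, GRCh38 chromosome 15, 74719542 to 74725610, minus strand) was 2.56 ± 0.16 (SE), with an edgeR Benjamini-Hochberg adjusted p = 0.000239. CYP1B1 (ENSG00000138061, chromosome 2, 38066973 to 38109902, minus strand) had a log2 fold change of 0.9955 ± 0.09 and an edgeR Benjamini-Hochberg adjusted p = 0.00526. CADM1 (ENSG00000182985, chromosome 11, 115169218 to 115504957, minus strand) had a log2 fold change of 0.78 ± 0.08 and an edgeR Benjamini-Hochberg adjusted p = 0.0118. CYP1A2 (ENSG00000140505, chromosome 15, 74748844 to 74756202, plus strand) had a log2 fold change of 2.09 ± 0.26 and an edgeR Benjamini-Hochberg adjusted p = 0.0349. Exons of CYP1B1 overlap those of RMDN2, RMDN2-AS1 and CYP1B1-AS1, and since the strand mode of the counting was not given in the sources used here, its count may leave out or include shared reads. The quasi-likelihood test of edgeR called 0 genes lower, against 3987 genes of either direction at an unadjusted p under 0.05, while DESeq2 called 92 lower and 84 higher and limma-voom called 0 lower and 4 higher.

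**Figure D1:**
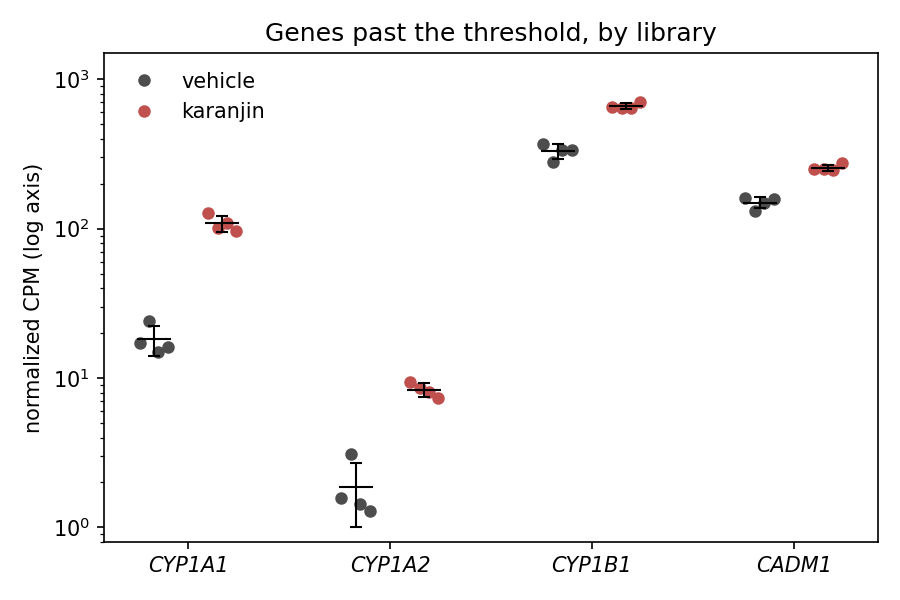
Normalized CPM (log axis) of CYP1A1, CYP1A2, CYP1B1 and CADM1 in each library, with vehicle in grey and karanjin in red; horizontal marks are group means and error bars are SD (n = 4). The 4 karanjin libraries lie above the 4 vehicle libraries for each gene, with CYP1A1 means of 18.2 and 108 CPM.

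The calls depended on single libraries to different degrees. In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, CYP1A1 passed when any 1 of the 8 libraries was left out, CYP1B1 passed in 7 of the 8 refits (adjusted p = 0.0581 without vehicle replicate 3), CADM1 in 3 and CYP1A2 in 1. By the same edgeR test with Benjamini-Hochberg adjustment, the gene CADM1 had an adjusted p of 0.13 without vehicle replicate 3 and of 0.0782, 0.0814, 0.0797 and 0.0576 without karanjin replicates 1 to 4. The gene CYP1A2 passed only without vehicle replicate 2 (edgeR Benjamini-Hochberg adjusted p = 8.22e-05). Its adjusted p by that test was 0.0957, 0.238 and 0.117 without vehicle replicates 1, 3 and 4, and 0.172, 0.2, 0.176 and 0.111 without karanjin replicates 1 to 4. In edgeR, 31 genes were called higher and 32 lower without vehicle replicate 2, 1 higher without vehicle replicate 3, and 2 higher without each karanjin replicate in turn.

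The fold changes followed the GC content of the transcripts, and vehicle replicate 2 stood apart. The log2 fold change correlated with transcript GC content across the genes tested with a Spearman rho of -0.715, where genes are not independent replicates. The slope of a library's log2 deviation per 10 points of GC was -0.028, 0.498, 0.162 and -0.017 in vehicle replicates 1 to 4, and -0.057, -0.207, -0.109 and -0.242 in karanjin replicates 1 to 4. The mean slope was 0.154 ± 0.246 (SD, n = 4) with vehicle and -0.154 ± 0.0856 with karanjin (exact permutation test, two-sided, p = 0.0286, the smallest this design allows). Without vehicle replicate 2, edgeR called 31 genes higher and 32 lower, and with each library's trend on GC content and transcript length removed it called 6 higher and 0 lower, with 2963 genes at an unadjusted p under 0.05. After that correction the log2 fold change was 2.73 for CYP1A1, 2.28 for CYP1A2 and 0.76 for CYP1B1, which still passed, and 0.48 ± 0.08 for CADM1, which did not (edgeR Benjamini-Hochberg adjusted p = 0.0872).

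**Figure D2:**
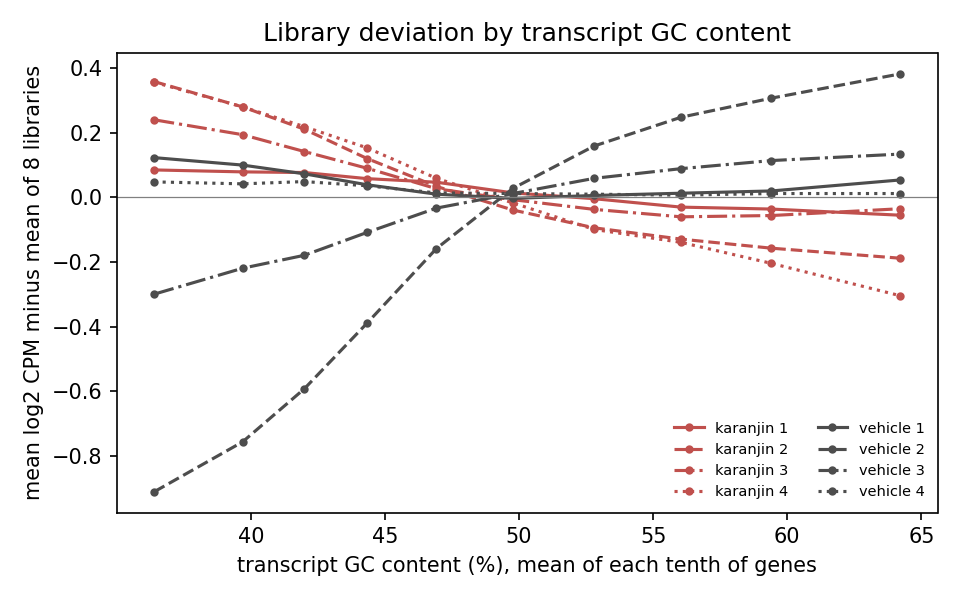
Mean log2 CPM of each library minus the mean of the 8 libraries, over 10 equal groups of the tested genes ordered by transcript GC content (percent); grey lines are vehicle and red lines karanjin libraries. Vehicle replicate 2 has the steepest slope, 0.498 per 10 points of GC, and the karanjin libraries slope downward, from -0.057 to -0.242.

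Whether the aryl hydrocarbon receptor programme moved as a group was asked with a list of its known targets, since flavonoids can bind this receptor. Of the 20 targets tested, 4 rose when adjusted over the list alone: CYP1A1, CYP1A2, CYP1B1 and NFE2L2, which encodes the antioxidant regulator NRF2. Adjusted over all genes, 3 rose. NFE2L2 had 32.1 CPM with vehicle and 46.3 CPM with karanjin, a log2 fold change of 0.54 ± 0.17. The receptor's own transcript AHR (36.1 and 41.9 CPM), its repressor AHRR (6.87 and 6.39 CPM) and the target TIPARP (26.6 and 43.9 CPM) did not pass in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment (adjusted p = 0.23, 0.66 and 0.15). Exons of AHRR overlap those of PDCD6 on the same strand, so its count is uncertain. The list was higher than the other genes by camera with Benjamini-Hochberg adjustment (adjusted p = 0.000833), and adjusted p = 0.135 with an estimated correlation. The median log2 fold change of its members was -0.0014 and the mean 0.34, and 10 of the 20 had a positive value. After the GC and length correction the median was 0.08, 13 of the 20 were positive, and 6 rose and 1 fell when adjusted over the list alone. Without vehicle replicate 2, 6 rose and 0 fell by that count, and with the correction as well 7 rose and 1 fell.

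Estrogen-responsive genes were examined because the cells were kept in hormone-stripped medium. Of 68 tested genes known to be induced by estradiol, 9 rose and 1 fell when adjusted over the list alone. Those that rose included the calcitonin receptor CALCR (log2 fold change 1.07 ± 0.16), the scaffold protein PDZK1 (1.01 ± 0.24), the progesterone receptor PGR (0.81 ± 0.16) and the chemokine CXCL12 (0.54 ± 0.10). PGR went from 586 ± 142 CPM (SD, n = 4) to 1025 ± 94.6 CPM. Over all genes PGR did not pass in edgeR with Benjamini-Hochberg adjustment, either without correction (adjusted p = 0.137) or after the GC and length correction (log2 fold change 0.35 ± 0.07, adjusted p = 0.114). It passed by that test without vehicle replicate 2 (adjusted p = 0.047), and with the correction as well (adjusted p = 0.00303). Over the 9 genes the corrected values lay between -0.05 and 1.11. Adjusted over the list alone, 12 rose and 1 fell without vehicle replicate 2, and 15 rose and 2 fell after the correction. The estrogen receptor transcript ESR1 stood at 421 ± 1.5 and 422 ± 17.4 CPM, and GREB1, an estrogen-induced coactivator, at 272 ± 18.3 and 287 ± 21.2 CPM; neither passed. TFF1 had 0.665 and 1.19 CPM, close to the level of 3 counts (0.246 to 0.428 CPM by library). At an unadjusted p under 0.05 in edgeR, 16 of the 68 were higher and 4 lower, a share close to that over all genes (3987 of 14565, either direction). Adjusted over all genes, edgeR called 0 of the 68, while DESeq2 called 6 higher and limma-voom 0. Over all genes edgeR called 5 of them higher without vehicle replicate 2, and 7 with the GC and length correction as well.

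The estrogen-induced list was higher than the other genes by camera with Benjamini-Hochberg adjustment (median log2 fold change 0.06, adjusted p = 0.0407), and adjusted p = 0.551 with an estimated correlation. Its call was lost without vehicle replicate 1 (camera, Benjamini-Hochberg adjusted p = 0.183), without vehicle replicate 4 (0.122) and without karanjin replicate 1 (0.193). By the same camera test with Benjamini-Hochberg adjustment, the adjusted p was 0.000371 without vehicle replicate 2 and 0.000234 after the GC and length correction, the latter 0.367 with an estimated correlation. Of 32 tested genes known to be lowered by estradiol, CYP1A1 rose, and TP53INP2 (log2 fold change -0.72 ± 0.11) and the receptor tyrosine kinase ERBB2 (-0.50 ± 0.10) fell, adjusted over the list alone; IGFBP5 had a log2 fold change of -0.27 ± 0.08 and did not pass. As a list they did not pass (median -0.17, mean 2e-04, test lower; camera with Benjamini-Hochberg adjustment, adjusted p = 0.266).

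Many genes of DNA replication had lower levels with karanjin, but vehicle replicate 2 stood apart from the other vehicle libraries. The mean log2 level of the S-phase list, centred over the libraries, was -0.184 in vehicle replicate 2, below the 4 karanjin libraries (-0.077 to -0.024), and 0.14, 0.066 and 0.16 in vehicle replicates 1, 3 and 4. Between the groups it differed by -0.091 (exact permutation test, two-sided, p = 0.286), and by -0.159 after the GC and length correction (exact permutation test, two-sided, p = 0.0286). Of 49 tested S-phase genes, 23 fell and 0 rose in edgeR when adjusted over the list alone. They included the ligase LIG1 (log2 fold change -0.57 ± 0.12), the helicase subunits MCM2 (-0.49 ± 0.10) and MCM3 (-0.32 ± 0.07) and the polymerase POLE (-0.33 ± 0.07). Over all genes edgeR called 0 of them, 27 were lower and 0 higher at an unadjusted p under 0.05, and DESeq2 called 8 lower and limma-voom 0. The count over all genes was 1 lower without vehicle replicate 2, and 3 with the GC and length correction as well. The list had a median log2 fold change of -0.25 (camera with Benjamini-Hochberg adjustment, adjusted p = 0.00047), and adjusted p = 0.0804 with an estimated correlation. The median was -0.22 without vehicle replicate 2 and -0.24 after the GC and length correction.

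Of 51 tested G2/M genes, 1 rose when adjusted over the list alone, the kinesin CENPE (log2 fold change 1.32 ± 0.27). NUF2 (0.98 ± 0.29), BORA (1.05 ± 0.34) and the kinase AURKB (-0.37 ± 0.12) did not pass. Over all genes edgeR called 0 of the 51, while DESeq2 called 1 higher and limma-voom 0. At an unadjusted p under 0.05 in edgeR, 8 were higher and 6 lower, a share close to that over all genes (3987 of 14565, either direction). Adjusted over the list alone, 2 rose without vehicle replicate 2 and 0 after the GC and length correction, where CENPE had a log2 fold change of 0.71. The list was higher by camera with Benjamini-Hochberg adjustment (median 0.25, adjusted p = 0.0261), and adjusted p = 0.551 with an estimated correlation. The median was 0.09 without vehicle replicate 2 (camera, Benjamini-Hochberg adjusted p = 0.123) and 0.03 after the GC and length correction (adjusted p = 0.037).

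Both lists of lipid synthesis genes were lower by camera with its preset correlation, but not with an estimated correlation. Of 24 tested genes of cholesterol synthesis, 11 fell and 0 rose when adjusted over the list alone. The lanosterol synthase LSS had a log2 fold change of -0.50 ± 0.10, the sterol sensor INSIG1 -0.39 ± 0.08 and TM7SF2 -0.43 ± 0.10. With the GC and length correction these values were -0.32, -0.49 and -0.12. Of 20 tested genes of fatty acid synthesis and lipid storage, 9 fell and 0 rose when adjusted over the list alone. The fatty acid synthase FASN went from 1829 to 1169 CPM (log2 fold change -0.65 ± 0.11), followed by the desaturases FADS2 (-0.64 ± 0.11) and SCD (-0.34 ± 0.07) and by SREBF1 (-0.63 ± 0.12), whose protein drives lipid synthesis genes.

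Over all genes edgeR called 0 members of either lipid list, against 13 lower cholesterol genes and 9 lower lipogenic genes at an unadjusted p under 0.05, and DESeq2 called 3 and 5 of them lower and limma-voom 0. Without vehicle replicate 2, edgeR called 2 cholesterol and 4 lipogenic genes lower over all genes, and 2 and 5 with the GC and length correction as well. The cholesterol list had a median log2 fold change of -0.27 (camera with Benjamini-Hochberg adjustment, adjusted p = 0.00216), and adjusted p = 0.245 with an estimated correlation. The lipogenesis list had a median of -0.15 (camera with Benjamini-Hochberg adjustment, adjusted p = 0.00899), and adjusted p = 0.135 with an estimated correlation. Without vehicle replicate 2 the medians were -0.20 and -0.08, and after the GC and length correction -0.19 and -0.16.

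Of 35 tested genes of hypoxia and glycolysis, 13 fell and 0 rose when adjusted over the list alone. The prolyl hydroxylase EGLN3 had a log2 fold change of -0.74 ± 0.13, the regulators PFKFB3 -0.48 ± 0.09 and NDRG1 -0.38 ± 0.09, and the pyruvate kinase PKM -0.33 ± 0.08. Over all genes edgeR called 0, with 18 lower and 1 higher at an unadjusted p under 0.05, and DESeq2 called 2 lower and limma-voom 0. Leaving out vehicle replicate 2, edgeR called 2 lower over all genes, with or without the GC and length correction. The list had a median of -0.24 (camera with Benjamini-Hochberg adjustment, adjusted p = 0.0017), and adjusted p = 0.389 with an estimated correlation. The median was -0.16 without vehicle replicate 2 and -0.17 after the GC and length correction. Of 51 nuclear genes of the respiratory chain, NDUFS7 (-0.69 ± 0.14) fell when adjusted over the list alone, while ATP5F1E (-0.29 ± 0.09) and COX5B (-0.43 ± 0.14) did not pass. That list had a median of -0.15 (camera with Benjamini-Hochberg adjustment, adjusted p = 0.00346), adjusted p = 0.551 with an estimated correlation, and a median of -0.07 without vehicle replicate 2. After the GC and length correction its median was -0.14 (camera with Benjamini-Hochberg adjustment, adjusted p = 0.000207), and NDUFS7, at -0.43, no longer passed over the list alone.

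Luminal epithelial genes and immediate early genes made up the remaining lists past the threshold. Of 33 luminal genes, 9 fell and 1 rose when adjusted over the list alone, among them the transcription factor ELF3 (log2 fold change -0.52 ± 0.09), the keratin KRT18 (-0.40 ± 0.10) and the protease ST14 (-0.39 ± 0.10). Of 26 immediate early genes, 4 fell when adjusted over the list alone: JUNB (-0.50 ± 0.14), JUND (-0.44 ± 0.12), the phosphatase DUSP4 (-0.36 ± 0.09) and JUN (-0.34 ± 0.10). By camera with Benjamini-Hochberg adjustment both lists were lower (medians -0.15 and -0.15, adjusted p = 0.0254 and 0.0345), and for both the adjusted p = 0.551 with an estimated correlation. Adjusted over the list alone, 6 luminal genes fell and 1 rose without vehicle replicate 2, and 1 fell and 0 rose after the GC and length correction. Of the immediate early genes, 2 fell and 1 rose in each of these fits. Over all genes without vehicle replicate 2, edgeR called 0 immediate early genes lower and 1 higher. This was IER3 (log2 fold change 0.38, edgeR Benjamini-Hochberg adjusted p = 0.0449). After the GC and length correction the medians of the luminal and immediate early lists were -0.03 and -0.09. Neither list then passed by camera with Benjamini-Hochberg adjustment (adjusted p = 0.563 and 0.463). The corrected log2 fold change was -0.37 for ELF3, -0.19 for KRT18 and -0.11 for ST14. It was -0.17 for JUNB, -0.07 for JUND, -0.32 for DUSP4 and -0.13 for JUN. Without vehicle replicate 2 the immediate early list did not pass (camera, Benjamini-Hochberg adjusted p = 0.129), and without karanjin replicate 2 neither did (0.0554 and 0.0559).

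In all, 3 lists were higher and 7 lower of the 27 tested. With an estimated correlation, camera with Benjamini-Hochberg adjustment called 0 higher and 0 lower without the GC correction, and with the GC and length correction it called the aryl hydrocarbon receptor list higher (adjusted p = 0.0487) and the S-phase list lower (adjusted p = 0.0169). By contrast fry, which tests whether the members of a list move one way, called the aryl hydrocarbon receptor, estrogen-induced, S-phase, cholesterol, lipogenesis and hypoxia lists and that of glucocorticoid, progesterone and androgen receptor targets. It does not compare a list with other genes, and it was run on these data without the GC correction only. In simulated counts with the measured GC trends, uncorrected, fry called 1 of 26 unchanged lists and camera with its preset correlation 0. Genes were drawn independently there, so the simulation cannot show whether the preset correlation is large enough for these data. In the real counts, camera with that correlation also called 10 lists when vehicle replicates 1, 3 and 4 with karanjin replicate 2 were set against the rest.

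**Figure D3:**
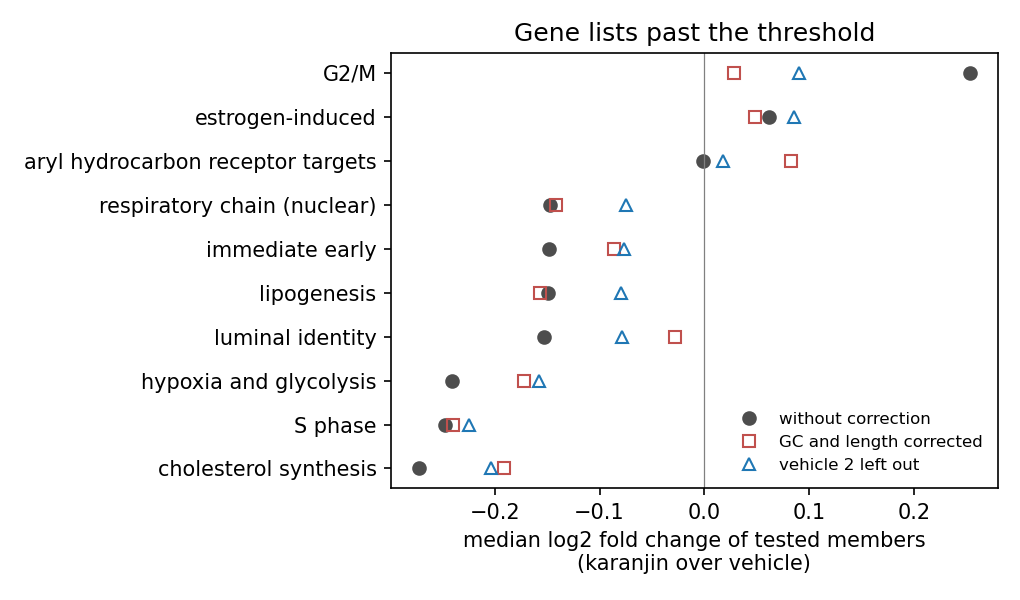
Median log2 fold change (karanjin over vehicle) of the tested members of the 10 lists past the threshold, without correction (filled circles), after the GC and length correction (open squares) and without vehicle replicate 2 (open triangles). The S-phase list lies at -0.25, -0.24 and -0.22 in turn, and the G2/M list at 0.25, 0.03 and 0.09.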

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

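Of the tests in this part, the splits of all 8 libraries for the count of genes, of genes changed 2-fold and of lists were planned, while the splits after the GC and length correction, without vehicle replicate 2 and for single lists, and the tests of the GC trend and of shared reads, were chosen only after the result was seen; the fit without vehicle replicate 2 was planned, and its use to weigh these patterns was chosen after.

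Single libraries far from the other 3 of their group were found in 9 of 134 groups of 4, where chance gives about 1 in 20. Vehicle replicate 2 stood apart for CYP1A2 (3.12 CPM, others 1.28 to 1.57), NFE2L2 (21.2 CPM, others 34.8 to 37.3), NDUFS7 (17.2 CPM, others 12.9 to 13.6) and COX5B (81.5 CPM, others 56.0 to 59.5). Karanjin replicate 4 stood apart for CADM1 (274.7 CPM, others 247.6 to 251.6), TFF1 (0.466 CPM, others 1.39 to 1.499) and the second principal component (27.1, others -4.10 to -0.33). Karanjin replicate 2 stood apart for DUSP4 (52.7 CPM, others 59.9 to 60.6) and OAS3 (91.2 CPM, others 101.5 to 102.6).

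After the GC and length correction the median log2 fold change of CYP1A1, CYP1B1 and CYP1A2 was 2.28 and each still passed, so a GC trend is argued against as the whole cause, and all 3 passed without vehicle replicate 2. The longest exact stretch that CYP1A1 and CYP1A2 transcripts share is 40 nt, against reads of 150 nt, which argues against reads of the first being counted for the second. Of the 35 splits of the libraries into 4 and 4, only the real one gave as many genes (4, highest other 0). The same held for genes changed 2-fold (2, highest other 0) and after the correction (6, highest other 0). A share of 1 of 35 is the smallest the design allows, so it argues against chance for these counts but cannot exclude it. For the aryl hydrocarbon receptor list, only the real split of the 35 gave a camera p as small (6.17e-05, smallest other 0.000465). This too is the smallest share the design allows, so chance is not excluded for that value. With an estimated correlation, camera with Benjamini-Hochberg adjustment gave adjusted p = 0.135, and 0.0487 after the correction. The list holds CYP1A1, CYP1B1 and CYP1A2 and was not tested without them, so it is not separate support for their rise. A candidate explanation is activation of the aryl hydrocarbon receptor by karanjin. These data do not separate it from slower clearance of another ligand, and neither was measured.

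The GC trend of the fold changes was weighed against vehicle replicate 2 and against library bias. Without vehicle replicate 2 the correlation with GC content was still -0.606, so that library is argued against as the sole cause. The vehicle libraries, which had no compound, differed in slope by up to 0.526, against -0.3075 for the karanjin mean minus the vehicle mean, but the slopes of the groups did not overlap, so a bias of the libraries and an effect of karanjin on GC-poor transcripts cannot be told apart. Leaving out vehicle replicate 2 gave 63 genes, but 2 of the 35 splits of the other 7 libraries gave as many (highest other 628, karanjin replicates 2, 3 and 4 against the rest, which differs from the real split by karanjin replicate 1 alone), and with the correction 3 of 35 gave the 58 genes or more (highest other 342), which points to a structure of the samples; chance is not excluded for these counts, and whether that structure is part of the treatment effect was not tested.

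The lower S-phase, cholesterol, lipogenesis and hypoxia lists kept over 50% of their median and their call after the correction in 4 of 4 cases, and 4 of 4 stayed past the threshold without vehicle replicate 2, which argues against either as the whole cause. With an estimated correlation after the correction, camera with Benjamini-Hochberg adjustment kept only the S-phase list of the 4 (adjusted p = 0.0169). The others had adjusted p = 0.15 for cholesterol, 0.103 for lipogenesis and 0.339 for hypoxia by that test. For the G2/M and luminal lists the larger share of the median kept after the correction was 18.2%. The luminal list no longer passed (camera, Benjamini-Hochberg adjusted p = 0.563), which goes with the GC trend as its source. The G2/M list still passed with the preset correlation (camera, Benjamini-Hochberg adjusted p = 0.037), though not with an estimated one (0.653). Between the groups its mean log2 level differed by 0.365 (exact permutation test, two-sided, p = 0.114). After the correction it differed by 0.161 (exact permutation test, two-sided, p = 0.171). Uncorrected and centred over the libraries, it was 0.11, -0.73, -0.233 and 0.123 in vehicle replicates 1 to 4. In karanjin replicates 1 to 4 it was -0.012, 0.286, 0.206 and 0.25. These levels do not separate the groups, and the source of the call is left open. Of the 35 splits, 2 gave 10 lists or more (highest other 10, vehicle replicates 1, 3 and 4 with karanjin replicate 2 against the rest), 9 gave a camera p as small for the estrogen-induced list (0.0151, smallest other 3.06e-08) and 5 for the S-phase list (1.74e-05, smallest other 6.33e-08), so chance is not excluded for these. After the correction only the real split gave 13 lists (1 of 35, highest other 10), whereas 4 splits, the real one included, matched the estrogen-induced list and 3 the S-phase list. The other splits matching the S-phase list, and those matching either list after the correction, each joined vehicle replicates 1, 3 and 4 with 1 karanjin library. They differ from the real split only by exchanging vehicle replicate 2 for that library, so they are not independent of it. A change in S-phase or lipid genes with karanjin may be real but stays open.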

How the results depend on the processing

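Of the settings in this part, the GC corrections, the fits without vehicle replicates 2 and 3 together, and those that join a correction or the replicate block with the loss of vehicle replicate 2 were chosen only after the result was seen. Over the 24 alternatives for single genes, CYP1A1 passed in 24, CYP1B1 in 20, CADM1 in 15 and CYP1A2 in 15, higher in each. Under the alternatives set before the data were seen, 994 of 1080 values of named genes, 349 of 378 of lists and 51 of 72 counts kept direction and side of the threshold or stayed within 1.5 times. Under those added later, 312 of 360, 127 of 189 and 17 of 24 did. Only 4 named genes passed in the main fit, so most gene values kept are of genes that stayed short of the threshold. A call was lost in 19 of the 1080 values, all of them of these 4 genes. Genes called were 34 higher and 33 lower (18 higher at 2-fold) with no filter, 84 and 92 (29) with DESeq2, 9 and 5 with the GC correction alone, 25 and 33 with the GC and length correction without vehicle replicate 2, and 11 and 7 without vehicle replicates 2 and 3. With 1 library left out they ranged from 1 to 31 higher, from 0 to 32 lower and from 1 to 5 higher at 2-fold. With the replicate block, 1 gene was called (1 at 2-fold), likewise with the stricter filter, and 2 with the block and the correction. Deviations from the group mean correlated at -0.42, -0.307, 0 and 0.218 between libraries of the same replicate number. After the GC and length correction these values were -0.262, -0.193, -0.001 and 0.076. They gave no sign of paired samples but cannot exclude pairing, which the sources used here do not state. The median of the estrogen-induced list was 0.0599 with the block, 0.0616 with an estimated correlation, 0.0484 with that and the correction, none of which passed, and 0.0371 to 0.0852 with 1 library left out. The aryl hydrocarbon receptor list did not pass with an estimated correlation (median -0.0014) and had medians of -0.0159 to 0.0531 with 1 library left out. Reversals of lists were first judged by the sign of the median, which gave 16 for the aryl hydrocarbon receptor list; after that was seen they were judged by the direction of the set test, which stayed higher for that list while its median lay between -0.0159 and 0.0827. By that rule the test's direction reversed for the following medians. With the GC and length correction these were inflammation -0.0041, interferon 0.0181 and ribosomal proteins -0.0032, the same with an estimated correlation. With the GC correction alone they were inflammation -6e-04, interferon 0.008, basal markers 0.018 and ribosomal proteins -0.031. With the replicate block and the correction they were -0.0034 for inflammation, 0.0285 for interferon and 1e-04 for ribosomal proteins. With the correction and without vehicle replicate 2 they were estrogen-repressed genes -0.0553, inflammation 0.0122, interferon 0.0013 and ribosomal proteins 0.0226. Ribosomal proteins stood at 0.0415 without vehicle replicates 2 and 3, and at 0.0188, with p53 targets at -0.033, with the replicate block and without vehicle replicate 2. With 1 library left out, ribosomal proteins ranged from -0.1001 to 0.0044 and ATF4 targets from -0.0439 to 0.0238. The log2 fold change of ESR1 was -0.0276 with upper-quartile scaling, -0.1772 with the GC and length correction, -0.1183 with GC alone, -0.17 with the correction and block, -0.0821 with the correction and without vehicle replicate 2, and -0.0154 to 0.0336 with 1 library left out. In the 4 corrected fits in that order AHR stood at -0.3174, -0.2652, -0.3011 and -0.1634, and in the first 3 AHRR stood at 0.0541, 0.1046 and 0.0452. The cause was not tested.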

Other observations

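Of the tests in this part, the 2 hypotheses were set down before their tests were run, and the values after the GC and length correction come from an alternative chosen after the result was seen.

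Among 36 interferon genes, IFIT5 rose (log2 fold change 0.79 ± 0.17) and OAS3 fell (-0.45 ± 0.09) when adjusted over the list alone, and the list did not pass (median -0.09, mean 0.03, test lower; camera with Benjamini-Hochberg adjustment, adjusted p = 0.527). After the GC and length correction IFIT5 had a log2 fold change of 0.29 and did not pass over the list alone, while 1 member fell. Among 27 apoptosis genes, the death receptor TNFRSF21 (-0.43 ± 0.09) and the survival factor BCL2L1 (-0.36 ± 0.09) fell when adjusted over the list alone (list, camera with Benjamini-Hochberg adjustment, adjusted p = 0.266), and after the correction 1 fell, with BCL2L1 at -0.14. Among 21 targets of glucocorticoid, progesterone and androgen receptors, 3 fell when adjusted over the list alone, SLC45A3 (-0.78 ± 0.19), TMPRSS2 (-0.48 ± 0.10) and NDRG1 (-0.38 ± 0.09), while PGR itself was higher by the count over its own list. ALDH1L2, a mitochondrial folate enzyme, rose among 37 ATF4 targets (0.88 ± 0.20), adjusted over the list alone. By that count 5 ATF4 targets rose without vehicle replicate 2, 5 after the correction and 7 with both.

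Lists that did not pass in camera with Benjamini-Hochberg adjustment had adjusted p = 0.0681 for the glucocorticoid, progesterone and androgen receptor targets, 0.109 for NRF2 targets, 0.183 for autophagy and lysosome, 0.192 for inflammation, 0.266 for drug metabolism, 0.266 for ribosome biogenesis, 0.422 for the unfolded protein response, 0.477 for mesenchymal genes and 0.482 for replication histones. Those of the ATF4, heat shock, p53, ribosomal protein and basal epithelial lists each had adjusted p = 0.615 by the same camera test with Benjamini-Hochberg adjustment; for the p53 and basal lists the median was below 0 (-0.08 and -0.03), the mean above it (0.0017 and 0.0046) and the test lower. Of 9 basal epithelial markers, SFN (-0.47 ± 0.10) and ITGB4 (-0.41 ± 0.11) fell when adjusted over the list alone, but after the GC and length correction both stood at -0.18 and 0 markers passed over the list alone. The markers of leukocytes summed to between 3.22 and 6.41 CPM per library, those of endothelial cells to between 30.8 and 61.7, those of fibroblasts to between 286 and 463 and the metallothioneins to between 44.8 and 84.6.

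With the GC and length correction, camera with Benjamini-Hochberg adjustment called 5 lists that it did not call without it. The ATF4 (adjusted p = 0.00857), heat shock (0.0158) and ribosome biogenesis (0.00311) lists were higher, and the apoptosis (0.0477) and the glucocorticoid, progesterone and androgen receptor (0.044) lists lower. With an estimated correlation these had adjusted p = 0.318, 0.481, 0.339, 0.45 and 0.45 by camera with Benjamini-Hochberg adjustment.

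After the GC and length correction, 3 further genes passed in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment: the early response gene IER3 (log2 fold change 0.53, adjusted p = 0.0207), the amino acid transporter SLC7A5 (0.47, adjusted p = 0.0435) and the long noncoding RNA LINC02568 (0.84, adjusted p = 0.0347). IER3 belongs to the immediate early list, which was lower by camera without the correction. LINC02568 and SLC7A5 were chosen after their values were seen.

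A hypothesis was that S-phase and G2/M genes moved apart rather than together. The mean log2 level of the S-phase list minus that of the G2/M list, after the correction and centred over the libraries, was 0.16 ± 0.141 (SD, n = 4) with vehicle and -0.16 ± 0.08 with karanjin (exact permutation test, two-sided, p = 0.0286, the smallest this design allows). Since these lists were compared because camera had already called them in opposite directions in the same libraries, the test adds no separate evidence and leaves the question open. The difference was 0.328 in vehicle replicate 2 and 0.045 and 0.041 in vehicle replicates 1 and 4, against -0.043 in karanjin replicate 1. The phase of the cells was not measured.

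A hypothesis was that the estrogen-induced list was higher only through the 3 members it shares with the aryl hydrocarbon receptor list. With these left out, limma's camera test over the 65 other genes gave an unadjusted p of 0.000399 in the corrected counts. This argues against the hypothesis in those counts, although other splits of the libraries gave smaller values for the whole list. In the uncorrected counts the unadjusted camera p was 0.0285, against 0.0151 for the whole list, whose call rests on adjustment over the lists. The glucocorticoid, progesterone and androgen receptor list, with an unadjusted camera p of 0.0278, did not pass (Benjamini-Hochberg adjusted p = 0.0681). The uncorrected value was not adjusted in this way, so it leaves the hypothesis open. These p-values rest on the preset correlation, and with an estimated correlation the whole list did not pass in camera with Benjamini-Hochberg adjustment (adjusted p = 0.367 corrected and 0.551 uncorrected).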
